A study of Mus musculus with 12 samples.

How the data were processed

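ATAC-seq had been run on nuclei of 100000 sorted cells per library from Treg and Tconv of WT and KO Foxp3-GFP reporter mice, with 3 libraries in each of 4 groups. Groups and replicate numbers were taken from the sample titles. Each list was assigned to its library as recorded in the deposit. Sample numbers inside the peak names run in another order (1 in WT Treg replicate 1, 4 in KO Tconv replicate 1) than the numbers the lists were deposited under, and which order is the original one is not given in the sources used here. One deposited list of broad peaks per library was used, with no pooled list. The submitters' processing notes name Trim Galore 0.4.4, Bowtie2, MACS2, DiffBind and DESeq2, with no role or order, and the genome build NCBIM37. Versions of the other tools, control input, read filters and whether cut sites were shifted are not given in the sources used here. DiffBind and DESeq2 were not run here, since the lists hold no counts.

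Each deposited peak carries a fold ratio over background, a −log10 p, a −log10 q and a score from the authors' peak caller. These values belong to the peak in its own list, and p grows with library depth. They were used only to describe, rank or filter peaks within a list, and comparisons between libraries used presence alone. The lowest −log10 p was about 5 in every list (mean 5.03 ± 0.0169, SD, n = 12), so a region just under that limit in one library reads as absent. The depth of the libraries is unknown, and the lists cannot tell a weaker signal from an absent one.

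Peaks of all 12 libraries were merged where they overlapped or touched, and regions with a peak in at least 2 libraries were kept. A library had a region when at least 1 bp of a peak lay in it. A region was Treg-enriched or Tconv-enriched when at least 5 more libraries of that cell type had a peak (6 against 6). It was lost or gained in KO when all 3 libraries of one genotype and none of the other had a peak, within a cell type. Coordinates are 1-based on NCBIM37. Fisher's exact tests were two-sided with BH adjustment, and permutation tests enumerated every labeling. Jaccard separation was the mean index within groups minus that between groups, tested one-sided. Intervals for shares are exact 95% Clopper-Pearson intervals and cover counting error only. The regions named are the 5 per direction with the highest mean within-list percentile of −log10 p, and every region absent from all KO or all WT libraries. The regions of the chromosome 7 stretch were named after their values were seen. Groups, calls, naming and most alternatives were fixed before the data were examined.

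The calls were tested on simulated presence data for 32787 regions with 200 changed. In the cell type comparison, 76% of simulated Treg and 95% of simulated Tconv regions were recovered and 46 unchanged regions were called. Fisher's exact test adjusted over testable regions called 0 regions in that simulation. In the genotype comparison, 80% of lost and 11% of gained regions were recovered in Treg, with 309 unchanged regions called, and 77% of each in Tconv, with 187 unchanged regions called. The low recovery of gains in Treg followed from the yield of KO Treg replicate 2, which was kept in the main comparisons and left out as an alternative.

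Alternatives were stricter peaks (−log10 q of at least 5), equal numbers of top peaks per library, coverage of at least 50% of a region, a minimum of 3 libraries or none, joining across gaps of up to 200 bp, autosomes alone, other thresholds, pairing by replicate number and leaving out each library. No genome or annotation of NCBIM37 was used here. The gene table used, with 49997 genes, is of GRCm38.p6 and served only to name the chromosome of Lrrc32. The planned gene list enrichment, cell type markers, motif content and peaks around Lrrc32 were therefore not run, and regions are given by position. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.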

Results

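Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase cuts accessible DNA, in 12 libraries of mouse splenic CD4+ T cells. Regulatory T cells (Treg), marked by a GFP reporter of Foxp3, the lineage-defining transcription factor of these cells, were sorted apart from GFP-negative conventional T cells (Tconv). The animals were wild type (WT) or lacked an enhancer 70 kb from Lrrc32 (KO). Lrrc32 encodes GARP, which holds latent TGF-beta on the Treg surface. Each of the 4 groups had 3 libraries of 100000 sorted cells. The labels do not say that every library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

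WT Treg libraries held 25401, 27605 and 22883 peaks, and WT Tconv libraries held 24019, 24546 and 21269. KO Tconv libraries held 24874, 24649 and 25283 peaks. KO Treg replicates 1 and 3 held 24689 and 25400, against 5262 in KO Treg replicate 2. The means were 25296 ± 2363 in WT Treg, 18450 ± 11427 in KO Treg, 23278 ± 1760 in WT Tconv and 24935 ± 321 in KO Tconv (SD, n = 3 each). Read depth was not given in the sources used here, so the number of peaks stands in for the yield of a library. With 3 libraries against 3 the smallest possible p is 0.1, so no difference in the number of peaks could pass 0.05. Every KO Tconv library had more peaks than every WT Tconv library (exact permutation p = 0.1, two-sided, n = 3 per group). The KO and WT Treg ranges overlapped (exact permutation p = 0.4), as did those of Treg and Tconv in WT (exact permutation p = 0.4) and in KO (exact permutation p = 0.7). Benjamini-Hochberg (BH) adjusted values over these 4 comparisons were 0.4, 0.533, 0.533 and 0.7. Without KO Treg replicate 2, the KO Treg mean was 25045 ± 503 (SD, n = 2).

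**Figure D1:**
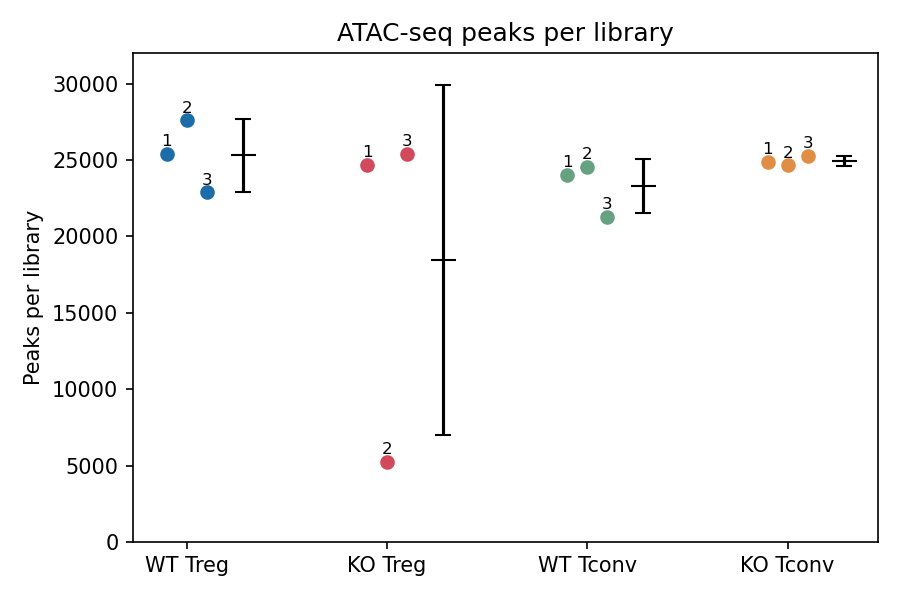
Number of peaks in each library (points, with the replicate number) by group on the horizontal axis, with the mean and SD (n = 3) in black. KO Treg replicate 2 has 5262 peaks, and the other 11 libraries have between 21269 and 27605.

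The 275880 peaks merged into 40457 regions, of which 32787 had a peak in at least 2 libraries and were kept. Their median width was 750 bp. Many regions were shared by nearly all libraries: 14780 regions (45.1%) had a peak in at least 11 of the 12 libraries, and 10272 of these lacked a peak in KO Treg replicate 2 alone. Shared regions had a median width of 1035 bp and a median peak percentile of 67.9 within the lists, where peaks are ranked by the authors' −log10 p. Regions enriched in one cell type, defined in what follows, had median widths of 692 bp (Treg) and 641 bp (Tconv) and median percentiles of 36.8 and 33.6. Regions merged from more peaks tend to be wider by construction. The percentiles also follow in part from the selection, since regions near the calling limit are missed in some lists.

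Treg and Tconv differed, by presence of a peak, at a small part of the 32787 regions. A peak was found in at least 5 more Treg than Tconv libraries at 1050 regions, and in at least 5 more Tconv than Treg libraries at 1163. Of the Treg-enriched regions, 41 had a peak in all 6 Treg and no Tconv library. Another 994 lacked a peak in KO Treg replicate 2 alone among the Treg libraries and in every Tconv library, and 15 had a peak in all 6 Treg libraries and 1 Tconv library. Of the Tconv-enriched regions, 534 had a peak in all 6 Tconv and no Treg library. With KO Treg replicate 2 left out and a difference of at least 4 libraries, the counts were 2034 and 2096.

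The 5 Treg-enriched regions with the highest mean percentile lay on chromosome 16 from 33606781 to 33607472, chromosome 12 from 35705427 to 35706557, chromosome 2 from 83540576 to 83541453, chromosome 5 from 151025880 to 151026678 and chromosome 9 from 7509727 to 7510448. Their percentiles were 89.6 ± 2.60 (SD, n = 5 libraries), 86.4 ± 8.26 (n = 6), 85.7 ± 9.25 (n = 6), 83.7 ± 4.97 (n = 6) and 80.8 ± 7.13 (n = 5). The regions on chromosomes 12, 2 and 5 had a peak in all 6 Treg libraries, and those on chromosomes 16 and 9 lacked one in KO Treg replicate 2. None had a peak in a Tconv library.

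The 5 Tconv-enriched regions with the highest mean percentile lay on chromosome 16 from 31181885 to 31182254 and chromosome 15 from 3259462 to 3260481, and on chromosome 2 from 83856091 to 83857122, from 117833664 to 117834183 and from 84422256 to 84423069. All 5 had a peak in every Tconv and no Treg library. The chromosome 16 region had a percentile of 95.7 ± 1.92 (SD, n = 6), and its fold enrichment over background, as the authors' peak caller gave it, ranged from 12.4 to 15.7 between libraries.

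A region with a peak in 6 of 6 libraries of one cell type and 0 of 6 of the other has a Fisher's exact p of 0.00216, and a difference of 5 libraries one of 0.0152 (two-sided). BH adjustment over all 32787 regions left 0 regions, with a smallest adjusted p of 0.123, while 2213 had an unadjusted p under 0.05. Over the 5679 regions present in 5 to 7 libraries, the only ones that could reach that threshold, all 1050 and 1163 passed, with Fisher's exact test adjusted p of 0.0214 at 6 against 0 and 0.0389 at a difference of 5. That restriction was chosen after the data were seen.

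**Figure D2:**
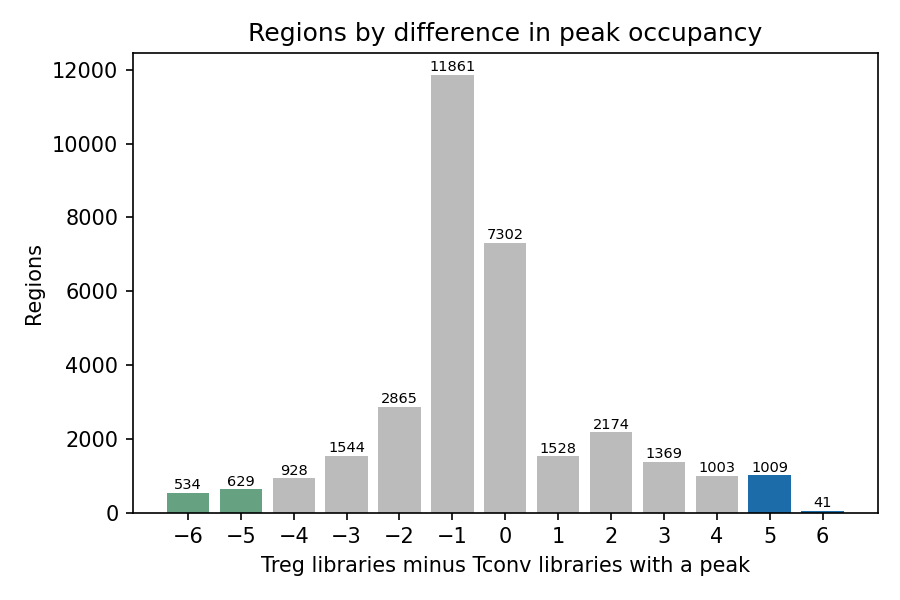
Regions (vertical axis, number) by the number of Treg minus Tconv libraries with a peak (horizontal axis), with Treg-enriched regions in blue and Tconv-enriched regions in green. The bar at −1 holds 11861 regions, and 10272 regions lack a peak in KO Treg replicate 2 alone.

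Whole peak sets separated by cell type as well. The Jaccard index, the base pairs shared by 2 peak sets over those covered by either, averaged 0.553 between libraries of one cell type and 0.492 between cell types, a difference of 0.0612 (exact permutation of cell type within genotype, 400 labelings, p = 0.005, one-sided). Without KO Treg replicate 2 the averages were 0.638 and 0.562. Pairs with that library had indices between 0.118 and 0.163.

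**Figure D3:**
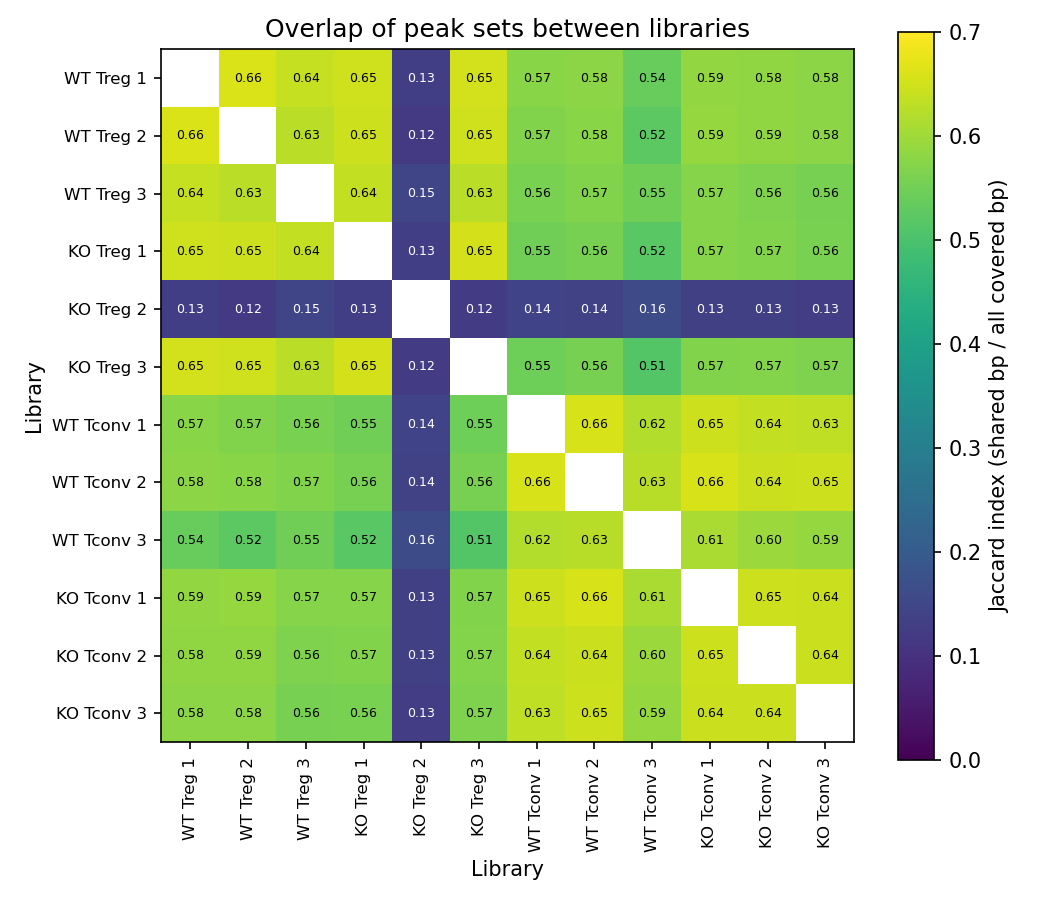
Jaccard index for each pair of the 12 libraries, from 0 (dark) to 0.7 (yellow). Without KO Treg replicate 2, pairs of one cell type lie between 0.589 and 0.660 and pairs across cell types between 0.512 and 0.589.

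The comparison of KO with WT asks which open regions depend on the enhancer. Across both cell types, a single region had a peak in all 6 WT and no KO library, on chromosome 16 from 45192616 to 45192978. It ranked at a percentile of 20.3 ± 11.5 (SD, n = 6) in the WT lists. One region had a peak in all 6 KO and no WT library, on chromosome X from 122212912 to 122214071, at a percentile of 10.9 ± 11.2 (SD, n = 6). This region lies in the interval of chromosome X with more KO peaks that is described at the end. With only stricter peaks (−log10 q of at least 5) both counts were 0, and at 50% coverage neither of these regions met the rule. Fisher's exact test with BH adjustment called 0 of the 5679 testable regions, with 22 at an unadjusted p under 0.05, of which 12 had more WT and 10 more KO libraries. The smallest Fisher's exact p a region can have is 0.00216, so a few changed regions could not pass this adjustment. In the simulated cell type comparison with 200 changed regions the same test also called 0. The result here therefore does not show that no region changed.

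In Treg, 319 regions had a peak in all 3 WT and no KO library and 10 had a peak in all 3 KO and no WT library. Without KO Treg replicate 2 the counts were 320 lost and 355 gained, so the imbalance between the directions rested on that library. The lost regions with the highest mean percentile lay on chromosome 8 from 13705641 to 13706019 (71.0 ± 22.3), chromosome 6 from 103414916 to 103416248 (67.1 ± 14.2), chromosome 1 from 60473315 to 60474260 (58.7 ± 25.8), chromosome 12 from 117248951 to 117249368 (58.2 ± 25.9) and chromosome 11 from 120094015 to 120094303 (56.0 ± 16.8; SD, n = 9 each). All 5 also had a peak in all 6 Tconv libraries, of both genotypes. The highest-ranked gained regions lay on chromosome 17 from 35104434 to 35106573 (45.9 ± 32.9; SD, n = 8), chromosome 2 from 135783509 to 135783974 (36.5 ± 7.89; n = 3) and chromosome 3 from 41989972 to 41990741 (33.7 ± 14.8; n = 5). The others lay on chromosome X from 120272055 to 120272706 (20.7 ± 16.4; n = 8) and from 143707126 to 143707918 (18.7 ± 16.2; n = 8). Simulated data with roughly matched yields had 309 unchanged regions called lost or gained, against 329 here. The simulation scaled every region by one yield factor per library, whatever its strength. In the data, the share of regions with a peak in KO Treg replicate 2 rose with strength from 1.12% to 90.9%. The near match of the counts therefore does not show that the losses arose by chance. Of the 5 named lost regions, 3 met the rule with stricter peaks and 1 where peaks had to cover 50% of the region. Of the 5 named gained regions, 0 met it in either setting. At 21269 top peaks per library and without KO Treg replicate 2, all 5 lost regions kept a difference of 3 libraries. The gained regions then had differences of 1, 2, 2, 2 and 0, in the order named, of a possible 2.

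The share of Treg regions with a peak was as high in 2 of the 3 KO Treg libraries as in a left-out WT Treg library. Regions were defined from 2 WT Treg libraries with a peak and no WT Tconv library with one (2162 to 2804 regions, depending on the pair). The left-out WT Treg library had a peak in 77.6% of them on average, KO Treg replicates 1 and 3 in 79.1% and 80.9%, and KO Treg replicate 2 in 2.88%. KO Tconv libraries had one in 15.1% to 17.4%. For Tconv regions defined in the same way, the left-out WT Tconv library had a peak in 75.1% and the KO Tconv libraries in 76.1%, 68.7% and 75.7%. Jaccard indices in Treg averaged 0.473 both within and between genotypes (exact permutation p = 0.5, one-sided), and 0.645 and 0.644 without KO Treg replicate 2.

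Among the regions lost in KO Treg, the largest group within 100 kb was 4 regions on chromosome 7, the chromosome that carries Lrrc32 in the GRCm38.p6 gene table; this group was picked after the data were seen. They lay in a stretch from 105637431 to 105735112 with 8 regions, each with a peak in all 3 WT Treg libraries and in no Tconv library. The stretch ran on each side to the nearest region with a Tconv peak. Its outer parts therefore lack such peaks by construction. KO Treg replicates 1 and 3 had a peak in 4 of the 8, and KO Treg replicate 2 in 0. The regions without a peak in any KO Treg library ran from 105661791 to 105662145, from 105705321 to 105705931, from 105710837 to 105711903 and from 105734587 to 105735112. The third had the highest percentile of the 4, 53.2 ± 5.57 (SD, n = 3). The other 3 had percentiles of 35.8 ± 12.3, 6.43 ± 4.11 and 18.8 ± 11.1, in order of position. Of the 4 lost regions, 2 met the rule with stricter peaks, 3 at 50% coverage and 0 with 5262 top peaks per library. The last result was fixed in advance, since their WT peaks rank too low to be among the top 5262. At 21269 top peaks per library and without KO Treg replicate 2, the WT minus KO differences were 3, 0, 3 and 3 libraries, in order of position. Peaks remained in KO Treg replicates 1 and 3 from 105637431 to 105639031, from 105640277 to 105640698, from 105682634 to 105683904 and from 105728635 to 105729408.

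**Figure D4:**
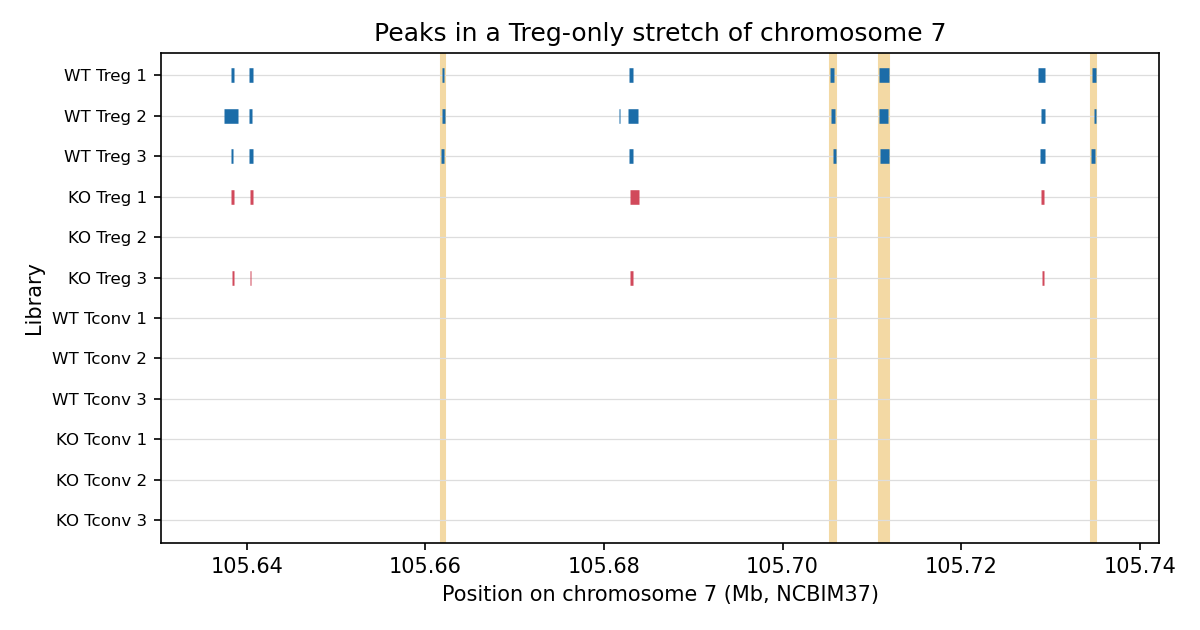
Peaks of each library (rows) along chromosome 7 in Mb (NCBIM37), drawn to scale, with WT Treg in blue and KO Treg in red. Shading marks the 4 regions with a peak in all 3 WT Treg and no KO Treg library, and no Tconv library has a peak in the stretch.

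In Tconv, 62 regions had a peak in all 3 WT and no KO library and 260 in all 3 KO and no WT library. At 21269 top peaks per library the counts were 118 lost and 141 gained, so much of the imbalance between the directions went with the number of peaks called. Leaving out single libraries gave 118 to 274 lost and 360 to 592 gained regions, with the highest number lost and the lowest number gained without WT Tconv replicate 3. The highest-ranked lost region was the whole mitochondrial sequence, 1 to 16299, called as 1 peak in each WT Tconv library and in WT Treg replicate 3, and as 3 peaks in KO Treg replicate 2. Its fold enrichment in the authors' lists was at most 1.21. The next was on chromosome 17 from 66307057 to 66307267, with a percentile of 49.7 ± 12.5 (SD, n = 3), followed by chromosome 13 from 73897401 to 73897895, chromosome 2 from 154836992 to 154837313 and chromosome 9 from 51716874 to 51717528. Gained regions ranked highest on chromosome 13 from 24578908 to 24579747 (69.0 ± 27.9; SD, n = 9), chromosome 2 from 9907428 to 9908195, chromosome 1 from 88290754 to 88291545, chromosome 16 from 97493661 to 97494329 and chromosome 14 from 87450854 to 87451900. All 5 had a peak in every WT Treg library. Of the named regions, 4 of 5 lost and 2 of 5 gained met the rule with stricter peaks, and 3 and 0 at 50% coverage. At 21269 top peaks per library and without KO Treg replicate 2, the difference stayed at 3 libraries in most named regions. The exceptions were the lost region on chromosome 9 and the gained region on chromosome 14, with 2 each. The Jaccard index averaged 0.640 within and 0.629 between genotypes (exact permutation p = 0.1, one-sided, the smallest the design allows). Simulated data with only roughly matched yields had 187 unchanged regions called lost or gained, against 322 here. The difference between these counts therefore does not show an excess.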

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

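The equal-number alternative without KO Treg replicate 2 and the adjusted test over testable regions were chosen after seeing the data. The cause was not tested except where the alternative's construction shows it. With 5262 top peaks per library, the counts were 119 Treg-enriched, 139 Tconv-enriched, 49 lost and 30 gained in KO Treg. With 21269 per library they were 118 lost and 141 gained in KO Tconv. With KO Treg replicate 2 left out and equal numbers of peaks, there were 2113 Tconv-enriched regions and 344 gained in KO Treg. Stricter peaks gave 3 gained in KO Treg, 155 gained in KO Tconv and 0 absent from every KO or every WT library. Coverage of 50% gave 695 Treg-enriched, 5 gained in KO Treg, 399 gained in KO Tconv and 0 absent from every WT library. On autosomes alone, 5 were gained in KO Treg and 0 absent from every WT library. A difference of at least 4 libraries gave 2053 Treg-enriched and 2091 Tconv-enriched regions, and 6 against 0 gave 41 and 534. Treg-enriched regions numbered 1879 in WT alone and 51 in KO alone (3 of 3 against 0 of 3). The KO count requires a peak in KO Treg replicate 2, of low yield. Tconv-enriched regions numbered 964 in WT alone and 1544 in KO alone, where the KO count requires no peak in that library. At least 2 of 3 against 0 of 3 gave 1381 lost and 379 gained in KO Treg, and 419 lost and 1145 gained in KO Tconv.

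Leaving out each library in turn gave 1148 to 2271 Treg-enriched and 1252 to 2710 Tconv-enriched regions, where a difference of 4 libraries is enough by construction. It gave 320 to 999 lost in KO Treg (lowest without KO Treg replicate 2), 11 to 355 gained in KO Treg (highest without KO Treg replicate 2), 118 to 274 lost and 360 to 592 gained in KO Tconv, 1 to 4 regions absent from every KO library and 1 to 3 absent from every WT library. With fewer libraries the rule is easier to meet. The Jaccard separation by cell type stayed between 0.0433 and 0.0793 and under an exact permutation p of 0.05 in each of these settings. The separation by genotype in Treg, −0.00047 in the main setting, ran from −0.0869 to 0.126. It was 0.00123 without KO Treg replicate 2, 2.34e-05 with stricter peaks and 0.00269 over regions. The mean Treg minus Tconv difference in peaks in KO ran from −9960 to 109.2, the highest without KO Treg replicate 2. The KO minus WT difference in Treg was −6846 peaks and −251.8 without that library. At the chromosome 7 region from 105637431, the WT minus KO Treg difference was 1 library in the main setting, −1 with stricter peaks, 0 with equal numbers of peaks and −1 with equal numbers and KO Treg replicate 2 left out. Over 15 results and 218 alternatives, 79 counts moved by over 1.5 times and 6 values changed sign. The other 133 were counts within 1.5 times, or differences of equal sign (and, for Jaccard, side of the threshold) whose size could still move. Some were fixed: a minimum of 3 libraries or none alters no count, and 3-against-3 tests cannot pass 0.05. For 40 named regions and 160 alternatives, the difference in libraries stayed equal in 74, moved in 84 and changed sign in 2. Of the 20 named regions lost or gained in KO, 9 met the rule with stricter peaks and 4 at 50% coverage. With 5262 peaks per library 1 did, the mitochondrial sequence, and several ranked too low to do so. At 21269 without KO Treg replicate 2, most kept a difference of 3, and those gained in KO Treg 0 to 2. Gene lists, markers and motifs were not run.

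Pairing by replicate number was checked by the correlation of deviations from group means between same-numbered libraries, which ran from −0.0283 to 0.0608, all under 0.1, so the numbers were not used as pairs; this does not show that no animals were shared. In WT the same-numbered Treg and Tconv libraries gave 0.0152 to 0.0608 against a mean of −0.0174 for different numbers, and in KO −0.0283 to 0.00841 against 0.00438. Deviations cancel within a group, so the mean for different numbers is no separate baseline. Not every library correlated best with its own number. With the replicate block, the enriched counts were 1050 and 1163, which the rule fixes by construction, and the Jaccard separation by cell type of 0.0612 had an exact permutation p of 0.0313. At least 2 of 3 pairs in one direction and none in the other gave 2543 lost and 392 gained in KO Treg, and 692 lost and 1825 gained in KO Tconv.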

Other observations

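All tests in this part were chosen after the results they bear on were seen.

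Enriched regions were grouped along chromosomes. Within 200 kb, 8 Tconv-enriched regions lay on chromosome 5 from 89357462 to 89552700, out of 9 regions in that span, and a group of that size occurred at a share of 0.005 among 1000 random draws. The largest Treg groups had 6 regions each (share of draws 0.0440). One lay on chromosome 1 from 145923162 to 146112406, out of 11 regions in that span. Another lay on chromosome 14 from 8313367 to 8491712, out of 6. The last lay on chromosome 6 from 15605840 to 15796155, out of 20. Of the Treg-enriched regions, 2.48% lay on chromosome 11, against 6.33% of the other regions present in 5 to 7 libraries (Fisher's exact test, adjusted p = 6.07e-06). On X lay 0.857% of them, against 3.35% of the others (Fisher's exact test, adjusted p = 3.52e-05). Chromosome 17 was also low (adjusted p = 0.00455), and chromosomes 16, 14 and 5 were high, with 5.81%, 5.90% and 7.33% against 3.74%, 3.89% and 5.14% (Fisher's exact test, adjusted p = 0.0335, 0.0406 and 0.0468). These tests treat neighbouring regions as independent.

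For the 2213 regions enriched in either cell type, chance as the source of the grouping is argued against: among 100 splits of the 12 libraries only the real one, 1 split, gave as many, and the highest other gave 1292. The 100 splits are not all that are possible. The share also takes Treg and Tconv libraries as separate, and same-numbered ones from a shared animal would allow fewer splits. For the 2 regions absent from every KO or every WT library chance cannot be excluded, since 33 of 100 splits with 3 libraries of each cell type on each side gave as many and the highest other gave 10. Within a cell type, 10 splits are too few for a share under 0.05. In Treg the real split gave 329 lost or gained regions, 4 of the 10 splits gave as many, and the highest other gave 515. In Tconv the real split gave 322, as the only 1 of the 10, and the highest other gave 237.

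KO Treg replicate 2 had few peaks. Regions of Tconv alone, defined without this library, had a peak in it in 0.559% of cases (exact 95% interval 0.115 to 1.62), against 3.96% (2.86 to 5.34) for regions of Treg alone, which argues against a Tconv library under a Treg label. Its mean Jaccard index was 0.139 with Tconv and 0.129 with Treg libraries over full lists, whose lengths differ, and 0.285 (0.279 to 0.291) with Tconv and 0.300 (0.293 to 0.311) with Treg at 5262 peaks per library. A lower depth or signal over background may account for the low yield: of 10 classes by rank of the regions shared by KO Treg replicates 1 and 3, the strongest had a peak in it in 90.9% of cases and the weakest in 1.12%. Depth and signal over background cannot be separated with peak lists.

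The 4 chromosome 7 regions lost in KO Treg may include the deleted enhancer, which the labels place 70 kb from Lrrc32. This was not tested, because the place of the gene in NCBIM37 was not used here. The peaks are absent not only from KO Treg replicate 2 but also from replicates 1 and 3, which held 24689 and 25400 peaks. Of 138 other Treg-only regions as strong in WT as the strongest one, 0 lacked a peak in KO Treg replicates 1 and 3 (exact upper 95% limit 2.64%). Such a loss is therefore rare at that strength. The strongest region was, however, picked for being lost and left out of this count. A peak near the calling threshold is therefore not excluded for it. For the other 3 this explanation stays open, because 7 of 457, 37 of 1014 and 45 of 1150 regions as strong also lacked such a peak (limits 3.13%, 4.99% and 5.20%). Random clustering also stays open, because the share of matched draws with as many regions depended on the window. For a group of 4 it was 0.0144 within 100 kb and 0.0537 within 200 kb. The 4 regions span 73.3 kb, so 50 kb cannot hold them all. The largest group of lost regions in that window was 3, with a share of 0.148. One deletion of all 4 is argued against by 2 regions between them with a peak in KO Treg replicates 1 and 3, and a shorter deletion was not tested.

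Between 120 and 123 Mb of chromosome X, KO libraries held more peaks: 139, 158 and 161 in KO Tconv against 79, 123 and 79 in WT Tconv, and 132, 58 and 133 in KO Treg against 97, 88 and 55 in WT Treg. The interval was picked as the 3 highest of 2320 bins of 1 Mb. It holds the region absent from every WT library, from 122212912, and a region gained in KO Treg, from 120272055. More peaks called in KO libraries is argued against in Treg, where KO replicates 1 and 3 held 24689 and 25400 peaks against 22883 to 27605 in WT. Without KO Treg replicate 2 and at 21269 top peaks per library, those 2 held 70 and 71 in the interval against 31 to 52 in WT Treg, a gap of 18. For KO Treg replicate 2, with 5262 peaks in all, an equal number decides nothing, because the other Treg libraries then held 0 or 1. The explanation stays open in Tconv, where the lowest KO library lay below the highest WT one (70 against 79, a gap of −9). At 21269 top peaks per library and without KO Treg replicate 2, the mean KO minus WT difference was 26.7 peaks in Tconv and 30.8 in Treg. The highest of many bins by chance is argued against as well: without KO Treg replicate 2, the real one alone of 200 labelings within cell type gave a bin as high (share 0.005, the smallest possible). This holds only if Treg and Tconv libraries are separate, since with same-numbered ones from a shared animal the share could not go below 0.05. Near-identical copies, copy number or strain at this interval cannot be told apart from an effect of genotype, as no mapping data bear on the 25 of its 176 regions with a peak in at least 3 more KO libraries; 0 had one in at least 3 more WT libraries, against 403 regions with more KO and 782 with more WT genome-wide.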
